A study of Caenorhabditis elegans with 6 samples.

How the data were processed

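Gene-level RSEM output was used as deposited, with 1 file per library. Expected counts are per the file headers, were not normalized by the authors and were rounded to whole numbers before testing. TPM were as deposited and served only in an alternative that tested log2(TPM + 1), with 1 added to avoid zeros. Gene lengths and effective lengths, in bases, are per the file headers and were used for length adjustment and an alternative offset. The deposited FPKM were not used. Per the submitters' processing notes reads were aligned with STAR 2.7.6a and quantified with RSEM, and the authors tested genes with DESeq2 1.26.0. The genome build and the annotation behind the counts are not given in the sources used here. Gene symbols and positions came from the Ensembl annotation release 115, which held 46817 of the 46904 identifiers, and 2887 genes had a sequence name but no symbol.

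Groups followed the labels, with 3 mutant and 3 wild-type libraries. Pairs of libraries differed by more than sampling noise (chi-square per degree of freedom 23.8 or more), so none was a library deposited more than once. That does not rule out a repeat preparation of 1 sample, which would also differ by more than counting noise, and each library counted as 1 sample because the labels list it as such. Merging wild-type libraries 1 and 2, whose titles differ only in a suffix, gave 2113 genes higher and 1634 lower. Genes were kept by edgeR's filterByExpr, which left 13250, and were tested by edgeR 4.0.16 with quasi-likelihood F tests and TMM scaling under R 4.3.3. The TMM factors were 1.27, 1.13 and 1.15 in mutant libraries 1 to 3 and 0.997, 0.649 and 0.933 in wild-type libraries 1 to 3, and the biological coefficient of variation was 0.248. A gene was called, and is said to have risen or fallen, when its p, adjusted by Benjamini and Hochberg over all tested genes, was under 0.05, and 2-fold counts used a log2 fold change of at least 1. Standard errors and intervals came from the same fits. Principal component 1 held 74.2% of the variance of log2 CPM.

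Gene groups, 45 in number, were written before the data were examined, as were the filter, the test, the thresholds and most alternatives. They were tested with camera in limma 3.58.1 at its preset correlation of 0.01 and with correlations estimated from the data, and with fry, given at least 3 tested members. The groups described in the report were chosen after their values had been seen. All lists' p-values were adjusted together.

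The named genes of a group were its 4 with the smallest p in the group's direction, and up to 2 called in the other direction. For the whole comparison they were the 15 with the largest change each way among called genes with a mean of at least 5 CPM and no overlap between the groups' values. mtx-2, mtx-1, gop-3, hsp-6 and hsp-60 were named whatever their values. Further genes were chosen after their values were seen and are identified as such where they appear.

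The length adjustment fitted, in each library, a loess curve with a span of 0.5 of the deviation in log2 CPM on log2 gene length, and entered the fitted values as offsets. It was chosen after the length trend had been seen, as were the counts of genes called in both fits, the tests of gene families and the RNA interference genes. It left a biological coefficient of variation of 0.214. It cannot tell a technical trend from a real difference between long and short genes, so unadjusted values are given beside adjusted ones.

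The alternatives were DESeq2 1.42.0, its size factors in edgeR, no composition factor, limma on log2(TPM + 1), other filters, effective length as an offset, each library left out in turn, blocks for the codes in the sample titles, and the removal of germline and sperm genes. Alternatives with length adjustment were added after the data had been seen.

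A simulation with 13250 genes checked the code. Without a length trend it recovered 34% of genes with a log2 change of 1 and 94% of those with 2, and called 7 of 13050 unchanged genes. With a trend put in, it called 547 unchanged genes, and 8 once the adjustment was applied. A muscle list that was shifted ranked 1 of 45, with 0 other lists called by camera. Genes were drawn there independently of each other and without a length trend. The rate of false list calls among genes that move together was therefore not checked. At this depth and spread, many changes of 2-fold or less would therefore be missed.

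GC content was not examined, because no genome sequence was at hand. Reads were not available, so transcripts, the deleted part of mtx-2 and microbial reads were not examined.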

Results

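RNA was sequenced from whole Caenorhabditis elegans larvae at the L4 stage, with 3 libraries from the mtx-2 mutant carrying the gk444 allele and 3 from the N2 wild type, each made from about 300 worms kept at 20 °C. The deposited expected counts summed to 28.1, 26.4 and 13.1 M in mutant libraries 1 to 3 and to 24.9, 25.1 and 23.9 M in wild-type libraries 1 to 3. A count was found for 17311, 17125 and 16358 genes in the mutant libraries and for 17037, 16260 and 16314 genes in the wild-type libraries. Of the 46904 genes listed, 13250 had enough counts to be tested. The libraries are numbered for reference only and have no order. The labels do not say that they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The title of wild-type library 1 is that of wild-type library 2 with a suffix, which may mark a repeat preparation and would leave 2 separate wild-type samples.

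mtx-2 encodes metaxin 2, a protein of the mitochondrial outer membrane that takes part in protein import and in the transport of mitochondria along axons. The gene (WBGene00022516, chromosome III, 7761977 to 7763603, minus strand, WBcel235) was detected in every library, with 1107, 888 and 513 counts in the mutant-labelled libraries and 902, 754 and 853 in the wild-type libraries. These were 30.9, 29.8 and 34.1 CPM (counts scaled to library size) against 36.3, 46.3 and 38.3, or 31.6 ± 2.22 against 40.3 ± 5.28 (mean ± SD, n = 3 per group). The log2 fold change was −0.35 (SE 0.17, 95% interval −0.74 to 0.04, edgeR adjusted p = 0.148), which did not pass the test, and it changed sign without composition scaling (0.14) and with limma on log2(TPM + 1) (0.35). Over the 24 alternatives its adjusted p ran from 0.104 to 0.687. A gene total does not show which part of a gene was read, so these values neither bear out nor contradict a partial deletion, and the labels were taken as given.

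Proteins that work with metaxin 2, and the reporters of mitochondrial stress, did not pass the test. mtx-1, the metaxin 1 gene, had a log2 fold change of −0.25 (SE 0.17, edgeR adjusted p = 0.265, n = 3 per group), which turned to 0.23 without composition scaling and 0.44 with limma on TPM. gop-3, the gene for the SAM50 beta-barrel insertion protein, stood at 0.24 (SE 0.20) and at −0.01 after length adjustment. vdac-1, the outer-membrane channel, stood at −0.63 (SE 0.26, edgeR adjusted p = 0.0940, all 3 mutant-labelled libraries below the wild-type mean) and at 0.09 with limma on TPM. The mitochondrial chaperones hsp-6 (−0.12, SE 0.21) and hsp-60 (−0.46, SE 0.22) did not pass either, stood above 0 without composition scaling (0.34 and 0.02) and with limma on TPM (0.60 and 0.26), and were called lower after length adjustment (−0.83 and −1.04). edgeR called 0 of the 4 genes of this metaxin group, with 1 at unadjusted p under 0.05, and DESeq2 called 1, vdac-1, lower.

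In the fit of all 6 libraries without length adjustment, worms labelled mtx-2 mutant had less RNA for cuticle collagens. They had more for genes of the intracellular pathogen response and for part of the F-box and MATH-domain genes, UDP-glucuronosyltransferases and cytochrome P450 genes. Of these groups fry called only the intracellular pathogen response and the F-box and MATH-domain genes (adjusted p = 0.0408 each). With an estimated correlation camera called none (adjusted p = 0.770). With and without length adjustment 9 UDP-glucuronosyltransferases and 12 cytochrome P450 genes rose, and their medians were 0.42 and 0.29 after it. Of 132 collagens tested, 60 fell, with a median log2 fold change of −1.07. Of 21 intracellular pathogen response genes tested 11 rose (median 1.02), as did 31 of 114 F-box and MATH-domain genes (median 0.58). So did 19 of 50 UDP-glucuronosyltransferases (median 0.77) and 15 of 54 cytochrome P450 genes (median 0.61). In that order the groups listed 176, 46, 347, 67 and 74 genes, and the rest had too few counts to be tested. Over all 13250 genes, edgeR with TMM scaling called 2124 higher and 1088 lower at an adjusted p under 0.05, of which 1732 and 399 changed by at least 2-fold. The smallest adjusted p was 0.0204, and 5841 genes had an unadjusted p under 0.05. The values of the groups did not overlap in 6928 of the 13250 genes. Arbitrary groupings give 10% of genes on average. Genes moved together, with principal component 1 holding 74.2% of the variance, so a single grouping can lie far above that average by chance. Called genes were 66.1% higher, a share that moved to 53.7% with DESeq2, 94.0% without composition scaling, 97.9% with limma on TPM and 43% after length adjustment. The median log2 fold change of all genes was 0.01 with TMM, 0.48 without composition scaling and 0.46 with limma on TPM.

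Long genes were higher and short genes lower in the mutant-labelled libraries. The median log2 fold change was −0.83 for the 520 genes up to 400 bases long and 1.93 for the 246 genes over 5000 bases, and gene length and log2 fold change had a Spearman correlation of 0.627. The slope of expression on length was 0.39, 0.30 and 0.14 in mutant libraries 1 to 3 and −0.16, −0.57 and −0.11 in wild-type libraries 1 to 3. After this trend was removed from each library the correlation was 0.0147, and edgeR called 1043 genes higher and 1380 lower. With and without this length adjustment, 925 genes were called higher both times and 417 lower both times, while 16 were called in opposite directions. A group whose members were called in both fits is therefore less open to this length trend than one called only without adjustment. Both fits used the same 6 libraries, so their agreement does not bear on outlying libraries.

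**Figure D1:**
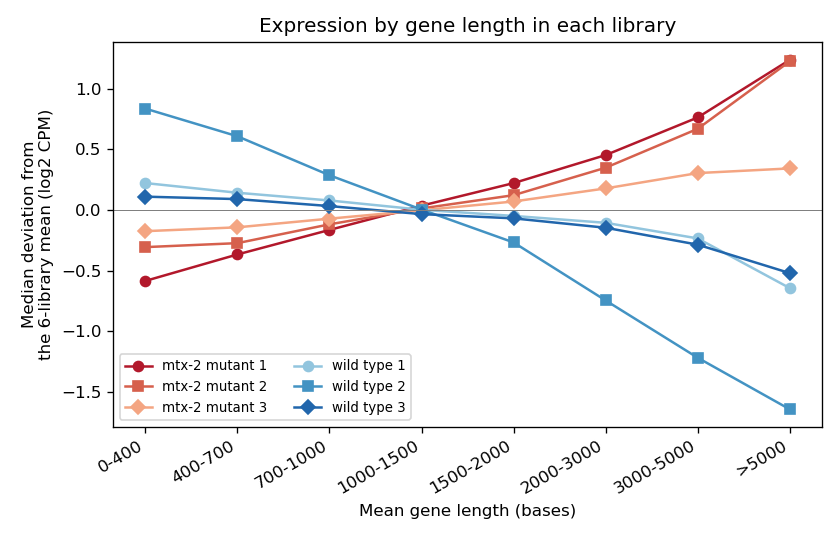
Median deviation of each library from the mean log2 CPM of the 6 libraries (vertical axis) against gene length in bases (horizontal axis, 8 bins), with 1 line for each of the 3 mutant-labelled and 3 wild-type libraries. Wild-type library 2 had the steepest fall with length, with a slope of −0.57.

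The counts of called genes rested on mutant libraries 1 and 2. Without mutant library 1 edgeR called 0 genes (3814 at unadjusted p under 0.05), and DESeq2 called 1112 higher and 516 lower. Without mutant library 2 edgeR called 0 genes (4192 at unadjusted p under 0.05), and DESeq2 called 1286 higher and 713 lower. Without mutant library 3 there were 1767 higher and 408 lower, and without wild-type library 1 there were 1057 higher and 1069 lower, with 1009 and 627 by 2-fold. Without wild-type library 2 the genes higher and lower by 2-fold numbered 1090 and 145, and without wild-type library 3 they numbered 1929 and 869. The counts shared by both fits became 773 higher and 133 lower without mutant library 3, 417 and 531 without wild-type library 1, 581 and 271 without wild-type library 2, and 1140 and 505 without wild-type library 3. They were 0 without mutant library 1 or 2.

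Of the 45 gene groups fixed before the data were examined, limma's camera called 5 higher and 15 lower at its preset correlation between genes. The higher ones were the intracellular pathogen response, F-box and MATH-domain genes, UDP-glucuronosyltransferases, cytochrome P450 genes and nuclear hormone receptors. With an estimated correlation none of the 20 kept its call (adjusted p = 0.770 to 0.772 with an estimated correlation, 1 group at unadjusted p under 0.05). limma's fry, which asks whether the genes of a group move one way on balance, called 2 groups higher, the intracellular pathogen response and the F-box and MATH-domain genes (adjusted p = 0.0408 each), and 0 lower, with 9 lower at unadjusted p under 0.05. After length adjustment camera called 4 groups higher and 12 lower, and again none kept its call (smallest adjusted p = 0.782 with an estimated correlation).

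**Figure D2:**
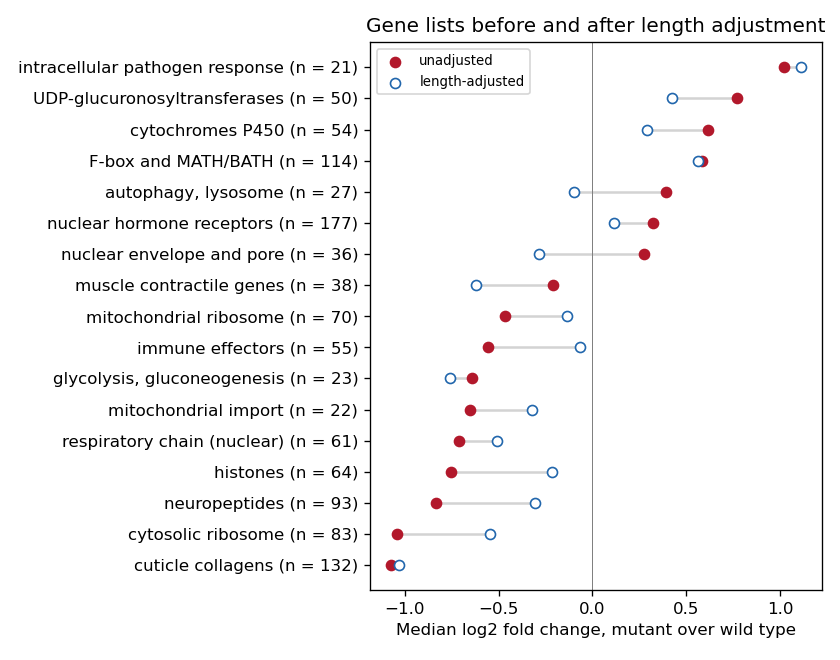
Median log2 fold change, mutant-labelled over wild type (horizontal axis), of 17 gene groups (vertical axis), without length adjustment (filled points) and after it (open points), from 3 libraries per group. Collagens stayed at −1.03 and intracellular pathogen response genes at 1.11 after adjustment.

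Collagens build the exoskeleton that the worm renews at each moult. The 60 collagens that fell became 73 when adjusted over the list alone, and 57 fell in both fits. col-12 fell from 689 ± 120 to 259 ± 16 CPM (mean ± SD, n = 3 per group; log2 fold change −1.41, SE 0.20, edgeR adjusted p = 0.0204). col-13 (−1.31, SE 0.23), col-156 (−1.29, SE 0.17), col-161 (−1.22, SE 0.17) and col-162 (−1.22, SE 0.17) fell to a like extent, and col-129 fell further, by 2.49 (SE 0.63). col-19, a collagen made mostly by adults, had a log2 fold change of −3.15 (SE 0.94) but missed the call after length adjustment. bli-1, a collagen of the adult cuticle struts, was the only member higher (0.96, SE 0.23), and its sign turned after length adjustment (−0.04). camera gave an adjusted p of 1.99e-17 for lower collagens (1.90e-41 to 4.59e-11 over the alternatives; adjusted p = 0.770 with an estimated correlation). The median stayed below 0 without composition scaling (−0.54) and with limma on TPM (−0.21). Mean deviations from the average of the 6 libraries were −0.68, −0.30 and −0.38 in mutant libraries 1 to 3 and 0.40, 1.15 and −0.20 in wild-type libraries 1 to 3, so wild-type library 2 carried much of the difference and wild-type library 3 lay near the mutants. The median was −0.78 without wild-type library 2. There were 36 lower collagens without mutant library 3, and without mutant library 1 or 2 edgeR made no call. Many collagens are near-identical, so the values of single members are uncertain.

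The intracellular pathogen response is a programme of genes that worms switch on against viruses and microsporidia. All 11 members called higher were called in both fits, and 13 rose when adjusted over the list alone. cul-6, a cullin of a ubiquitin ligase in this response, rose from 0.600 ± 0.220 to 4.30 ± 1.01 CPM (mean ± SD, n = 3 per group; log2 fold change 2.80, SE 0.34, edgeR adjusted p = 0.0204). pals-30 (2.85, SE 0.50), pals-24 (1.52, SE 0.30) and pals-39 (2.15, SE 0.45) rose as well. Mean deviations were 0.52, 0.81 and 0.37 in mutant libraries 1 to 3 and −0.35, −0.76 and −0.60 in wild-type libraries 1 to 3. The median stayed between 0.79 and 1.48 under every alternative, with camera's adjusted p at 5.31e-05 (3.51e-10 to 0.00176 over the alternatives; adjusted p = 0.770 with an estimated correlation). Without wild-type library 1 7 members rose, and without mutant library 1 or 2 edgeR made no call. These genes had few counts, and reads can be shared among the pals paralogs.

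Many F-box proteins bring substrates to cullin ubiquitin ligases, and MATH-domain genes were listed with them. Of the 114 genes tested 31 rose, 37 when adjusted over the list alone, with 1 lower, and 28 rose in both fits, while none of 20 genes of the bath family, which join a BTB to a MATH domain, was called in both fits. fbxa-105 rose from 2.82 ± 0.360 to 7.70 ± 0.514 CPM (mean ± SD, n = 3 per group; log2 fold change 1.44, SE 0.22). math-26 (2.91, SE 0.46), math-3 (2.48, SE 0.39) and fbxa-98 (1.45, SE 0.27) rose in both fits. The median was 0.56 after length adjustment. Without wild-type library 1 18 members rose, and without mutant library 1 or 2 edgeR made no call. Paralogs in these families are similar enough to share reads.

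**Figure D3:**
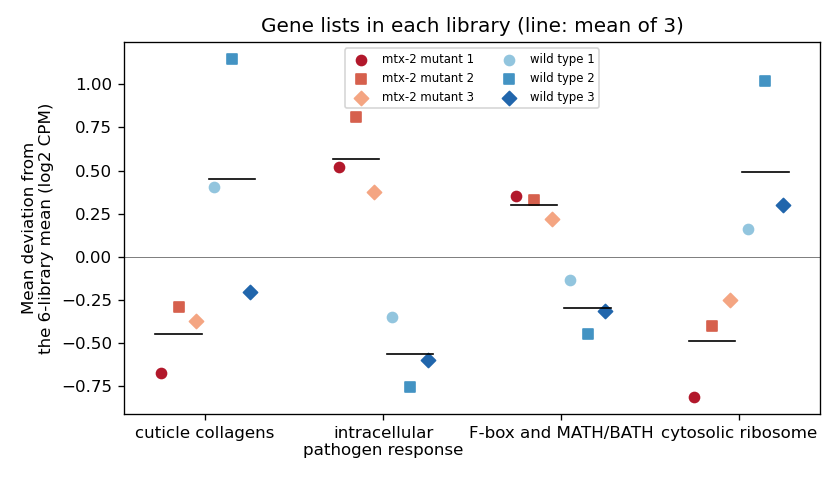
Mean deviation from the average log2 CPM of the 6 libraries (vertical axis) for collagens, intracellular pathogen response, F-box and MATH-domain and cytosolic ribosome genes (panels), with a point for each library and a line at the mean of 3. Wild-type library 2 was the highest for collagens, at 1.15.

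UDP-glucuronosyltransferases and cytochrome P450 enzymes modify and clear foreign and internal small molecules. ugt-44 rose from 16.6 ± 3.38 to 62.7 ± 6.58 CPM (mean ± SD, n = 3 per group; log2 fold change 1.92, SE 0.21), and ugt-39 (1.79, SE 0.34), ugt-23 (1.12, SE 0.21) and ugt-24 (2.08, SE 0.40) rose in both fits. Of the UDP-glucuronosyltransferases 28 rose and 1 fell when adjusted over the list alone, 9 rose in both fits, and the median was 0.42 after length adjustment. cyp-35A2 rose from 12 ± 2.25 to 28.6 ± 2.12 CPM (log2 fold change 1.24, SE 0.20), and cyp-29A2 (1.56), cyp-43A1 (1.17) and cyp-25A2 (1.63) rose in both fits. Of the cytochrome P450 genes 17 rose when adjusted over the list alone, 12 rose in both fits, and the median was 0.29 after length adjustment. Without wild-type library 1 9 UDP-glucuronosyltransferases and 7 cytochrome P450 genes rose. Of 35 glutathione transferases 4 fell, 2 when adjusted over the list alone and 2 in both fits, with a median of −0.45 that turned to 0.0508 without composition scaling and 0.17 with limma on TPM while camera still placed them lower. That call was lost after length adjustment (median −0.17) and with an estimated correlation (adjusted p = 0.770 with an estimated correlation), and 1 glutathione transferase fell without mutant library 3. Of 35 genes of oxidative defence 5 fell and 3 rose, but 1 and 1 when adjusted over the list alone and 1 and 1 in both fits, with a median of −0.34 that turned to 0.15 without composition scaling and 0.35 with limma on TPM and was −0.17 after length adjustment. In the unadjusted fit of all 6 libraries camera placed them lower (adjusted p = 0.0411, and 0.0196 to 0.596 over the alternatives). That call was lost after length adjustment and with an estimated correlation (adjusted p = 0.770 with an estimated correlation). Of these oxidative defence genes 1 fell without mutant library 3, and the higher calls were lost without wild-type library 1.

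Nuclear hormone receptors are transcription factors, some of which control detoxification and lipid genes. Of 177 tested 23 rose, a smaller share than the 2124 of all 13250 genes, and 3 fell, with a median of 0.32, and 15 rose and 3 fell in both fits. In the length-adjusted fit 15 rose and 14 fell. nhr-232 (1.90, SE 0.36), nhr-153 (2.17, SE 0.41), nhr-107 (1.81, SE 0.37) and nhr-104 (1.16, SE 0.25) were called higher in both fits, and nhr-58, nhr-270 and nhr-119 were the 3 that fell. With edgeR 0 passed when adjusted over the list alone, 57 had an unadjusted p under 0.05, and DESeq2 called 28 higher and 8 lower. camera's adjusted p was 0.00954 (0.00288 to 0.419 over the alternatives; adjusted p = 0.772 with an estimated correlation), and the call was lost after length adjustment (median 0.11), without mutant library 1 and without wild-type library 2. The number that rose was 12 without mutant library 3, 4 without wild-type library 1 and 9 without wild-type library 2.

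Many genes of the cytosolic ribosome, and a smaller part of the nuclear genes for mitochondria, fell before adjustment, but few were called in both fits. Of 83 genes of the cytosolic ribosome, with a median length of 533 bases, 68 fell, 82 when adjusted over the list alone and 5 in both fits, and the median went from −1.04 to −0.55 with length adjustment. rps-5 fell from 3991 ± 1368 to 1704 ± 334 CPM (mean ± SD, n = 3 per group; log2 fold change −1.23, SE 0.30) in both fits, while rpl-43 (−1.33, SE 0.31), rps-27 (−1.15, SE 0.29) and rps-30 (−1.15, SE 0.29) fell only without adjustment. Only 13 of the 83 fell without mutant library 3. The group's median stayed below 0 under every alternative (−1.235 to −0.27). camera placed the group lower (adjusted p = 4.845e-21, and 2.738e-11 after length adjustment). With an estimated correlation it did not (adjusted p = 0.770, and 0.801 after length adjustment). Ribosomal protein genes held 15%, 17.6% and 19.7% of the counts in mutant libraries 1 to 3 and 23.1%, 27.3% and 23.8% in wild-type libraries 1 to 3.

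Of 61 nuclear genes of oxidative phosphorylation 26 fell, 49 when adjusted over the list alone and 5 in both fits, with a median of −0.71 that turned to 0.02 with limma on TPM, although camera still placed them lower (adjusted p = 0.770 with an estimated correlation). After length adjustment the median was −0.51, with 15 lower. ndua-5 (−0.94, SE 0.24), hpo-18 (−0.92, SE 0.24), ndub-7 (−1.01, SE 0.27) and ndub-2 (−0.92, SE 0.25), parts of complexes I and V, fell without adjustment. Only 5 of them fell without mutant library 3. Of 70 genes of the mitochondrial ribosome 20 fell and mrpl-1 rose (1.19, SE 0.35), with 27 lower and 1 higher when adjusted over the list alone and 6 lower and 1 higher in both fits, and the median of −0.47 turned to 0.02 without composition scaling and 0.25 with limma on TPM. After length adjustment it was −0.13, which ended camera's call, and 0.0194 without wild-type library 3 as well. With adjustment, camera called the group lower again without wild-type library 1 (adjusted p = 0.0087) or 2 (0.0372). The unadjusted call was also lost with an estimated correlation (adjusted p = 0.770). mrpl-41 (−1.06, SE 0.21) and mrpl-39 (−1.0, SE 0.23) fell in both fits, and mrpl-36 (−1.12, SE 0.26) and mrpl-55 (−0.86, SE 0.21) only without adjustment. Without mutant library 3 9 of them fell, and without wild-type library 3 12 fell. For the 12 genes of the mitochondrial genome edgeR called 0, 2 had an unadjusted p under 0.05, and DESeq2 called 2 lower. Their median of −0.79 turned to 0.20 with limma on TPM and rested on wild-type library 2 (mean deviation 1.53, against −0.51 and −0.0518 in wild-type libraries 1 and 3): without it the median was −0.0845, and 0.0801 after length adjustment. edgeR called 1 lower without wild-type library 1 and 3 without wild-type library 3. Of 26 genes of the citric acid cycle and pyruvate dehydrogenase 1 rose and 1 fell before adjustment, 13 fell after it and 1 fell in both fits. Their median went from −0.40 to −0.75 with length adjustment. camera placed them lower in both fits (adjusted p = 0.0427 and 8.07e-05), but not with an estimated correlation (adjusted p = 0.772 and 0.801).

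Protein import into mitochondria is the process in which metaxins act. Of 22 genes tested 10 fell and 2 rose, with 13 lower and 2 higher when adjusted over the list alone and 3 lower and 1 higher in both fits, and the median of −0.65 turned to 0.08 with limma on TPM while camera still placed the group lower. Its call was lost after length adjustment (median −0.32) and with an estimated correlation (adjusted p = 0.770 with an estimated correlation). timm-23, the channel of the inner membrane, fell from 262 ± 79.5 to 122 ± 19.8 CPM (mean ± SD, n = 3 per group; log2 fold change −1.1, SE 0.25, edgeR adjusted p = 0.0238, all 3 mutant-labelled libraries below the wild-type mean). timm-17B.1 (−0.96, SE 0.22) also fell in both fits, and tin-9.1 (−1.05, SE 0.23) and tin-10 (−0.86, SE 0.22), small chaperones of the space between the membranes, fell only without adjustment. tin-44, part of the import motor, rose in both fits (1.69, SE 0.36), and tomm-70, a receptor for proteins to be imported, rose without adjustment (1.08, SE 0.31). Without wild-type library 1 the higher calls were lost and 14 members fell, and without wild-type library 2 1 rose and 8 fell.

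Some neuropeptide and histone genes, most of them short, fell before adjustment. Of 93 neuropeptide genes 40 fell, 67 when adjusted over the list alone and 4 in both fits, with a median of −0.83 that was −0.31 after length adjustment. nlp-24 (−1.09, SE 0.19), nlp-34, flp-32 (−1.46, SE 0.32) and nlp-81 (−1.1, SE 0.21) were among them, nlp-81 in both fits. Leaving out mutant library 3 left 25 lower. Of 64 histone genes 20 fell, 21 when adjusted over the list alone and 6 in both fits, with a median of −0.75 that turned to 0.01 with limma on TPM while camera still placed them lower (adjusted p = 0.770 with an estimated correlation), and that was −0.21 after length adjustment. The linker histones his-24 (−1.02, SE 0.21) and hil-3 (−1.17, SE 0.25) and the core histones his-40 (−1.41) and his-58 (−1.67) fell in both fits, although copies of core histones are near-identical and their single values uncertain. Without mutant library 3 11 histone genes fell, and without wild-type library 1 13 fell.

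Of 55 immune effector genes 12 fell and 5 rose, with the same numbers when adjusted over the list alone and 1 lower and 3 higher in both fits, and the median of −0.56 turned to 0.23 with limma on TPM while camera still placed the group lower. That call was lost with an estimated correlation (adjusted p = 0.770 with an estimated correlation) and after length adjustment, where the median was −0.0679 and camera's direction turned to higher. cnc-8, a caenacin antimicrobial peptide, fell from 66.8 ± 17.3 to 27 ± 2.94 CPM (mean ± SD, n = 3 per group; log2 fold change −1.31, SE 0.22) in both fits. nlp-34 (−0.98, SE 0.19), spp-31 (−0.98, SE 0.24) and nlp-27 (−1.12, SE 0.28) fell without adjustment. irg-1, a gene induced by bacterial infection, rose in both fits (0.90, SE 0.26), and irg-7 (1.22, SE 0.28) rose but turned to −0.53 after length adjustment. The number that fell was 4 without mutant library 3 and 7 without wild-type library 2, and 1 rose without each of these, against 2 without wild-type library 1 or 3.

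Sugar metabolism kept its direction when length was accounted for. Of 23 genes of glycolysis and gluconeogenesis 4 fell and 1 rose, also when adjusted over the list alone and in both fits, with a median of −0.64 that was −0.76 after length adjustment and turned to 0.08 with limma on TPM while camera still placed the group lower (adjusted p = 0.770 with an estimated correlation). fbp-1 (−0.84, SE 0.23) and pck-1 (−0.77, SE 0.23) of gluconeogenesis, tpi-1 (−0.89, SE 0.26), which acts in both pathways, and ldh-1, the lactate dehydrogenase (−0.87, SE 0.24), fell. pyk-2, a pyruvate kinase, rose (1.13, SE 0.26). Without wild-type library 3 7 members fell, and the lower calls were lost without mutant library 3.

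Nuclear envelope and autophagy genes, many of them long, had medians above 0 before adjustment and below 0 after it, and with all 6 libraries camera called neither group in either of these fits. With adjustment, camera called nuclear envelope genes lower when mutant library 2 or 3 or wild-type library 1 or 2 was left out, and the autophagy median was 0.0812 without mutant library 1 and 0.00943 without wild-type library 2. With limma on TPM camera called both groups higher (adjusted p = 0.0206 for nuclear envelope and 0.0237 for autophagy genes). With all 6 libraries, length adjustment and an estimated correlation, camera's adjusted p was 0.801 for each. Of 36 nuclear envelope genes 11 rose and 3 fell, 13 and 4 when adjusted over the list alone, and 2 rose and 2 fell in both fits. The median of 0.27 was −0.29 after length adjustment, where the balance turned to 2 higher and 12 lower. npp-21 (2.27, SE 0.38) and npp-14 (1.79, SE 0.37) of the nuclear pore rose without adjustment, lem-3 rose in both fits (1.69, SE 0.37), and anc-1, a giant protein that anchors nuclei and mitochondria, turned from 1.32 (SE 0.26) to −1.74. The pore genes npp-18 (−0.62, SE 0.19) and npp-20 (−0.60, SE 0.18) fell in both fits but stood at 0.09 and 0.11 with limma on TPM. Without wild-type library 1 5 members rose, without wild-type library 3 1 fell, and without mutant library 3 the lower calls were lost. Of 27 autophagy genes 10 rose, 11 with 2 lower when adjusted over the list alone and 5 in both fits. The median of 0.39 was −0.10 after length adjustment, where 5 rose and 4 fell. epg-5 (3.10, SE 0.44) and epg-8 (1.29, SE 0.27) rose in both fits, and atg-2 (2.5, SE 0.41) and let-363, the TOR kinase (2.42, SE 0.45), rose without adjustment. Without wild-type library 1 4 autophagy genes rose.

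Among 38 genes of body wall muscle 9 rose and 4 fell, 9 and 6 when adjusted over the list alone and 1 and 1 in both fits, with a median of −0.21 that turned to 0.28 without composition scaling and 0.49 with limma on TPM. After length adjustment the median was −0.62, with 1 higher and 8 lower, and camera called the group lower, but not so with an estimated correlation (adjusted p = 0.801 with an estimated correlation). The genes that rose were long ones such as unc-22 (3.11, SE 0.52) and ttn-1 (2.43, SE 0.38), giant kinases of the sarcomere, dys-1, the dystrophin gene (1.35, SE 0.29), and myo-3, a myosin heavy chain (1.42, SE 0.30), which stood at −0.26 after length adjustment. The short myosin light chain genes mlc-1 (−1.01, SE 0.29, also lower with adjustment) and mlc-2 (−0.99, SE 0.28) fell. The number that rose was 6 without wild-type library 2, and the number that fell was 7 without wild-type library 1, while without mutant library 3 the lower calls were lost.

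Among called genes with a mean of at least 5 CPM and no overlap between the groups, the 15 with the largest rise had log2 fold changes of 3.06 to 3.45, and all were long. They were the lipoprotein receptors lrp-1 (3.45, SE 0.63) and lrp-2 (3.28), the calcium release channel itr-1 (3.45, SE 0.57), the matrix and adhesion genes rig-4 (3.38), cdh-3 (3.37), epi-1 (3.24) and him-4 (3.22), the lipid transfer genes vps-13 (3.23) and lpd-3 (3.11), sdc-3 (3.15) of dosage compensation, unc-22, epg-5, trr-1 (3.07), the transporter ced-7 (3.07) and T24B8.7 (3.06). All but lrp-1, cdh-3, lrp-2, unc-22 and trr-1 rose in both fits. The 15 with the largest fall ran from −2.49 to −1.31 and comprised col-129, T04C12.17 (−1.50), F56C3.8 (−1.49), F23F12.12 (−1.47, SE 0.25), dod-3 (−1.42), col-12, nlp-26 (−1.4), col-184 (−1.38), R05D3.6 (−1.38, under 2 identifiers with identical values and so uncertain), rpl-43, F40H3.2 (−1.32, SE 0.21), col-13, F41F3.3 (−1.31, SE 0.27) and ZC395.5 (−1.31). Of these, the collagens, F23F12.12, F40H3.2 and F41F3.3 fell in both fits. Within 20 kb of mtx-2, 8 of 11 annotated genes were tested, and cdh-3 and pcp-1 (0.89, SE 0.27, edgeR adjusted p = 0.0449) rose, neither in both fits.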

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

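The gap between a gene's length and its effective length, which RSEM derives from fragment or read length, lay outside the comparisons made here. Its median over genes of more than 1000 bases was 190.5 bases in mutant library 1 and 167.9 in mutant library 2, above the highest wild-type value of 162.1. It was 158.0 in mutant library 3 and 162.1, 158.5 and 162.1 in wild-type libraries 1 to 3, so the gap did not separate the groups. Mutant libraries 1 and 2, with the largest gaps, also had the most positive length slopes (0.39 and 0.30). Without either of them edgeR called 0 genes. Whether the gap is tied to the length trend was not tested.

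The tests of library quality and genotype were chosen after the length trend was seen. Uneven RNA or library quality may account for the trend. Wild-type library 2 set against the other wild-type libraries, with no change of genotype, had a correlation of −0.563 between gene length and difference. That library was already known to have the steepest slope, so a strong correlation was bound to be found. The value shows that the trend also occurs within a genotype. It cannot tell quality from other differences between libraries. A difference in depth is unlikely, because the correlation of length with log2 fold change was 0.632 after every library was thinned to 13.1 M counts, with 1988 genes higher and 1065 lower. Genotype could neither be ruled in nor out, because the 3 mutant slopes all lay above the 3 wild-type slopes, yet an exact permutation test of 6 libraries cannot give a p below 0.1, the value found.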

How the results depend on the processing

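Besides mtx-2, 138 named genes were checked, of which 122 kept their sign under every alternative, and genes called in the comparison kept theirs in 92.9% to 100% of cases. Counts moved more. DESeq2 called 2084 genes lower, 618 by 2-fold. Without composition scaling 122 were lower, 2 by 2-fold. limma on TPM called 5036 higher and 108 lower, 3 of these by 2-fold, and 8 lists higher. Merging the library whose title carries a suffix with its namesake gave 1634 lower. Length adjustment gave 1043 higher, 655 by 2-fold. With camera's estimated correlation 0 lists were higher and 0 lower (1 at unadjusted p under 0.05), and with fry 2 were higher and 0 lower (9 lower at unadjusted p under 0.05). The cause was not tested. With each library left out in turn, with and without length adjustment, the counts ran from 0 to 2149 genes higher, 0 to 1562 lower, 0 to 1929 higher by 2-fold and 0 to 869 lower by 2-fold, and from 4 to 6 lists higher and 9 to 17 lower. The zeros came without mutant library 1 or 2.

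Samples share only a code in their titles and nothing says that they were paired. With that code as a block edgeR called 0 genes higher and 0 lower (0 and 0 by 2-fold; 5003 at unadjusted p under 0.05), also after length adjustment (4423), while DESeq2 called 1955 higher and 1331 lower. With the 2 matched pairs alone as a block edgeR called 0 higher and 0 lower (2821 at unadjusted p under 0.05), and DESeq2 called 319 and 49. In the 2 matched pairs, the libraries' deviations from their group means had correlations of 0.069 and −0.383. The other pairs of a mutant and a wild-type library ran from −0.546 to 0.493. After length adjustment with this block the log2 fold changes of gop-3, anc-1, myo-3, irg-7 and vit-1 were −0.0051, −1.75, −0.26, −0.54 and −0.80.

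Log2 fold changes reversed as follows. Without composition scaling the median of all genes rose from 0.01 to 0.48, and with limma on TPM to 0.46. Genes in general thus moved up in these settings, and other causes of the reversals were not tested. In the same settings log2 fold changes were 0.14 and 0.35 for mtx-2 and 0.0176 and 0.26 for hsp-60. They were 0.23 and 0.44 for mtx-1 and 0.34 and 0.60 for hsp-6. With limma on TPM they were 0.0893 for npp-18, 0.11 for npp-20 and 0.0939 for vdac-1. After length adjustment they were −0.0128 for gop-3, −1.74 for anc-1, −0.26 for myo-3, −0.042 for bli-1, −0.53 for irg-7 and −0.84 for vit-1. With each library left out, with and without length adjustment, they ran from −0.15 to 0.35 for gop-3, −1.02 to 0.0775 for hsp-6, −2.01 to 1.53 for anc-1, −0.41 to 1.67 for myo-3, −0.30 to 1.06 for bli-1, −0.71 to 1.34 for irg-7, −1.103 to 0.85 for vit-1, −0.14 to 3.51 for unc-22, −0.0592 to 2.67 for ttn-1, −1.11 to 0.0686 for tin-10 and −1.12 to 0.0169 for hpo-18. Depth limited how many genes could be tested, with 12175 left after every library was thinned to 13.1 M counts, against 13250.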

Other observations

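A few genes of RNA interference, picked after their values were seen because they rose in both fits, are given as values only, and no list of such genes was tested. dcr-1, the Dicer gene, had a log2 fold change of 2.91 (SE 0.41; 1.26 after length adjustment), the Argonaute rde-1 2.54 (SE 0.41; 1.53), the RNA-dependent RNA polymerase rrf-1 2.26 (SE 0.39; 1.67), and the helicases drh-1 2.11 (SE 0.39; 1.13) and drh-3 2.23 (SE 0.48; 1.15), with 3 libraries per group. Among 170 families defined by gene name after the data were seen, col genes were called lower in both fits more often than other genes (56 of 113, Fisher adjusted p = 9.97e-52, against 3.15% of all genes). These Fisher tests take genes as independent, but all calls rest on the same 6 libraries and collagens moved together (estimated correlation 0.486). Their p-values therefore do not measure the spread between samples. Genes called higher in both fits, 6.98% of all, were frequent in the math (10 of 16, Fisher adjusted p = 2.43e-06), pals (10 of 17, 3.68e-06), fbxa (18 of 77, 0.000358), cyp (12 of 54, 0.0157) and prp families (6 of 13, 0.00868), the last of these splicing factors such as prp-8 (2.58), but not clearly so in the ugt family (9 of 50, 0.219). Translation factors of the eif family were called lower in 5 of 25 (Fisher adjusted p = 0.0462), with eif-6 lower (−0.92) and eif-2D higher (1.98).

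Among the remaining groups, the genes named here were also chosen after their values were seen. Of 14 genes tied to the mitochondrial unfolded protein response 2 rose and 2 fell (5 and 2 when adjusted over the list alone), while 6 rose without wild-type library 3 and the higher calls were lost without wild-type library 1. There lonp-1, the matrix protease (1.96, SE 0.51), and the regulator dve-1 (1.08, SE 0.26) rose in both fits, timm-23 and ubl-5 fell, and the median of 0.39 was −0.03 after length adjustment. eat-3, which fuses inner mitochondrial membranes, rose in both fits (2.09, SE 0.45). In lipid metabolism 10 genes rose and 4 fell, 6 and 2 when adjusted over the list alone and 3 and 2 in both fits, and after length adjustment the balance turned to 3 and 9. The counts were 4 and 6 without wild-type library 1, 5 and 3 without wild-type library 2 and 5 and 2 without mutant library 3. Among them were acox-3 (1.73, SE 0.36) and lipl-7 (1.49, SE 0.31) higher and acs-2, an acyl-CoA synthetase (−0.94, SE 0.18), lower in both fits. Of 20 genes of endoplasmic reticulum stress 7 rose, 9 with 1 lower when adjusted over the list alone and 2 in both fits, with 4 higher without mutant library 3 or wild-type library 2 and 1 without wild-type library 1, and the median of 0.42 was −0.13 after length adjustment. The sensors ire-1 (1.70, SE 0.33, in both fits) and pek-1 (1.82, SE 0.41, without adjustment) rose. The mitochondrial thioredoxin reductase trxr-2 rose (1.53, SE 0.37), and the peroxiredoxin prdx-6 (−1.07, SE 0.24), the glutathione transferase gst-24 (−0.88, SE 0.20) and the succinyl-CoA ligase sucl-2 (−0.80, SE 0.24) fell, all in both fits. In the germ line syp-1 of the synaptonemal complex (1.69, SE 0.41) rose in both fits and glp-1, the Notch receptor (2.01, SE 0.39), without adjustment. ced-5, which helps to engulf dying cells, rose in both fits (2.22, SE 0.37), and the yolk gene vit-1 rose (0.74, SE 0.23) but stood at −0.84 after length adjustment. Of 91 moulting genes 17 rose and 9 fell, with 4 and 4 in both fits and 15 lower without wild-type library 3. Among them were qua-1 (2.17, SE 0.33), grl-4 (−1.12, SE 0.16) and grd-10 (−1.12, SE 0.18). After length adjustment 4 rose and 12 fell (median −0.33), and camera did not call the list (adjusted p = 0.06245). With adjustment, camera called it lower without mutant library 2 (adjusted p = 0.04735), mutant library 3 (0.04055) or wild-type library 3 (0.0123). It did not do so without mutant library 1 or wild-type library 1 or 2. For 28 major sperm protein genes, which are near-identical, edgeR called 0, 25 had an unadjusted p under 0.05, and DESeq2 called 25 lower, while without wild-type library 3 edgeR called 27 lower.

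The tests of collagens and of the intracellular pathogen response were chosen after those results were seen. A length trend is unlikely to account for the lower collagens, whose median log2 fold change was −1.03 after adjustment. A single library alone is also an unlikely source, since the median nearest to 0 with any library left out was −0.78. That cannot exclude a single sample if wild-type library 1 is a repeat preparation of wild-type library 2. The remaining wild-type library 3 (−0.20) lay near the mutants. A difference in developmental timing remains possible, because collagens come and go with each moult, but moulting genes were not over-represented among genes called in both fits (8 of 91, or 8.79%, against 9.80%; odds ratio 0.887, 95% interval 0.370 to 1.84, Fisher p = 0.861). Some groups that mark late larvae and adults, looked at after the result, followed collagens (0.40, 1.15 and −0.20) across wild-type libraries 1 to 3. Mean deviations were 0.39, 1.41 and −0.42 for major sperm proteins and 0.56, 1.3 and −1.25 for late cuticle genes (4 tested). They were 0.44, 0.56 and −0.74 for oocyte genes and 0.29, 0.40 and −1.05 for yolk genes (5 tested). In mutant libraries 1 to 3 major sperm proteins (−0.89, −0.27 and −0.22) lay low throughout, as collagens did. Late cuticle genes (−0.57, 0.15 and −0.18), oocyte genes (−0.37, 0.0744 and 0.0396) and yolk genes (0.41, 0.20 and −0.25) did not, so timing was left open. No test of mtx-2 loss itself as the cause was possible with 1 mutant strain.

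The rise of the intracellular pathogen response is unlikely to come from gene length, as its median was 1.11 after adjustment, or from a single library, as the median nearest to 0 was 0.84 with a library left out. Infection of the mutant cultures and a response to the mutation could not be told apart, because no reads of other organisms were at hand.

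The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.1. For genes higher, genes lower, the 2-fold counts and the counts after length adjustment, only 1 of 10 splits, the real grouping, reached its count, and in the others edgeR called at most 0 genes, with up to 877 at unadjusted p under 0.05. For lists higher 9 of 10 splits, and for lists lower 3 of 10, had as many calls by camera in a direction, with up to 17 lists in another split, so the number of lists called could be reached by an arbitrary grouping.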
